A study of Mus musculus with 18 samples.

How the data were processed

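RNA-seq was made from mouse macrophages grown from fetal livers taken on embryonic day 14 and cultured in medium conditioned by L929 fibroblasts, a source of macrophage colony-stimulating factor. Per the labels' protocols, the cells carried either the Rad21-TEV allele, in which recognition sites of the tobacco etch virus (TEV) protease are built into the cohesin subunit Rad21, or the wild-type gene. They were transduced with a retrovirus for TEV protease fused to ERT2, a mutated estrogen receptor domain that keeps its partner inactive until 4-hydroxytamoxifen (OHT) binds it. The brightest 20% of cells for the green fluorescent marker were sorted on day 10 in vitro. Cells received 500 nM OHT, or its solvent ethanol, for 8 h, and the stimulated samples then received lipopolysaccharide (LPS), a bacterial ligand of Tlr4, at 10 ng/ml for 2 more hours. Libraries were made from 100 ng of total RNA with a strand-marking kit, per the labels' protocols.

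The authors deposited 1 table of whole-number read counts per Ensembl gene and library, not normalized and not pooled over replicates. TopHat2 and the mouse build mm9 are named in the submitters' processing notes, without versions. The counting tool, its annotation and its strand setting are not given in the sources used here, so values of near-identical paralogs, of overlapping genes and of antisense genes are uncertain. The table lists 37620 genes, of which 37205 could be given a symbol from the reference annotation of the same build and 415 could not. At least 1 count was found for 24987 genes. Every count column matched the label of 1 sample, and 0 columns were left unmapped.

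The 18 libraries form 6 groups of 3. Rad21-TEV cells were given ethanol or OHT, each unstimulated or with LPS, and wild-type cells were given OHT, unstimulated or with LPS. No wild-type cells given ethanol are among these samples, so the effect of OHT itself cannot be separated from that of Rad21 cleavage within Rad21-TEV cells. Total counts ran from 41578018 to 93106366 per library. A gene with no counts in a library was below 0.0322 to 0.0722 CPM (counts scaled to a common library size), the limit that 3 counts set at these depths. Such limits and the intervals of ratios cover counting error only.

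Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 15936 of them, scaling factors were made by the trimmed mean of M values, and 1 model with a mean per group was fitted over all 18 libraries with glmQLFit and tested with glmQLFTest. Adjusted p-values are Benjamini-Hochberg values over the genes tested, and a gene was called at an adjusted p under 0.05. Levels are CPM after that scaling, given as mean ± SD over 3 libraries, and fold changes are on the log2 scale with their SE. The contrasts were OHT against ethanol in Rad21-TEV cells, unstimulated and with LPS; LPS against unstimulated in each of the 3 treatment arms; Rad21-TEV against wild-type under OHT, in both states; the 2 control arms (Rad21-TEV with ethanol and wild-type with OHT) against each other, in both states; and the differences between LPS responses. The contrasts, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The difference in LPS response between the 2 control arms was added afterwards.

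Genes were named by a fixed rule. In each contrast it took the 8 largest changes per direction among called genes with a mean of at least 1 log2 CPM and no overlap between the compared libraries, and up to 4 members of each fixed list with the smallest p. Predicted genes and sex-linked genes were not named, and some genes that the rule took are not reported here. Members of a list named outside this rule, where 5 or fewer were called, were chosen after their values were seen. The 22 lists held cohesin and its regulators, LPS early primary response genes, LPS secondary response cytokines and effectors, interferon-stimulated genes, type I interferon pathway components, macrophage identity genes, S phase genes, G2/M genes, p53 targets, sterol biosynthesis genes, LXR targets, immediate early genes, heat shock genes, unfolded protein response genes, glycolysis and hypoxia genes, and markers of neutrophils, erythroid cells, mast cells and progenitors, hepatocytes, dendritic cells with MHC class II, stroma with endothelium, and lymphoid cells. Each list was tested against all other genes with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 lists of a contrast. The test was repeated with the correlation estimated from the data. The early primary and immediate early lists share Fos, Egr1, Junb, Atf3 and Dusp1. Lists of genes at least 2-fold higher or lower with LPS in wild-type cells were taken from the contrast of the wild-type groups, in the fit over all 18 libraries, and tested with camera in the Rad21-TEV contrasts, without adjustment over contrasts.

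Replicates differed by more than sampling noise in every group (chi-square per degree of freedom 9.78 to 135), so no library was a copy of another. The labels do not say that replicates came from separate embryos, and p-values measure only the spread between these samples. Sex-linked genes separated the libraries numbered 2 of the Rad21-TEV cells from all others. Libraries with the same number also deviated together: over 10844 autosomal genes, deviations from group means correlated at 0.394 to 0.721 between same-numbered libraries of the 6 pairs of Rad21-TEV groups, at 0.406 to 0.607 in wild-type cells, and between different numbers at -0.00282 or less in Rad21-TEV cells and 0.0462 or less in wild-type cells. Deviations within a group sum to 0, so the low values between different numbers follow in part from the same-numbered ones. They are not separate evidence of pairing. From the same-numbered values, the numbers were taken to pair libraries within a genotype. A fit with the number as a block nested in genotype (the paired fit) was set beside the unpaired one.

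Alternatives were size factors from DESeq2 1.42.0, total counts alone, no filter, the DESeq2 Wald test, only the compared groups in the fit, blocks by number, another fold threshold for LPS-induced genes, and each library left out in turn. A fit without the 4 Rad21-TEV libraries numbered 2 was added after their sex-linked counts had been seen. It leaves 2 libraries in each Rad21-TEV group, so a call can be lost there without a change in fold change. The procedure was tested on simulated counts drawn from the real library sizes and each gene's mean over all libraries, without effects of LPS, genotype or pairing. The changed genes were picked only above a minimum level in unstimulated Rad21-TEV cells with ethanol. Recovery of genes below that level, such as genes nearly silent before LPS, was not tested. For OHT against ethanol in unstimulated Rad21-TEV cells, over 15725 genes, 42 of 60 genes changed by 1.5-fold were recovered (70.0%), 64 of 73 changed by 2-fold (87.7%) and 66 of 67 changed by 4-fold (98.5%), and 9 unchanged genes were called. For the difference in LPS response between OHT and ethanol, over 15708 genes, the same sizes gave 14 of 71 (19.7%), 38 of 65 (58.5%) and 61 of 64 (95.3%), with 7 unchanged genes called.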

Results

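Gene expression was measured in 18 macrophage libraries, 3 for each of 6 combinations of genotype, drug and LPS. Library 1 of LPS-treated Rad21-TEV cells with OHT was the deepest, at 93106366 counts, and the next held 54813889. Xist, the RNA that coats the inactive X chromosome in females, stood at 546 to 909 CPM in 14 libraries, while the Y-linked Ddx3y stayed at 0.0564 to 0.383 CPM there. In the 4 Rad21-TEV libraries numbered 2, Xist was at 0.382 to 0.657 CPM and Ddx3y at 94.4 to 115 CPM, so these are called the male libraries here. Mitochondrially encoded genes took a mean of 3.36% to 3.48% of counts in the 2 wild-type groups and 3.96% to 4.37% in the 4 Rad21-TEV groups.

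Rad21 (ENSMUSG00000022314, chromosome 15, 51794151 to 51823306, minus strand, mm9) encodes the subunit that closes the cohesin ring. Its mRNA was at 71.2 ± 4.29 CPM in unstimulated Rad21-TEV cells with ethanol, 68.3 ± 3.43 with OHT and 151 ± 5.26 in wild-type cells with OHT (SD, n = 3). With LPS the same groups stood at 98.5 ± 9.19, 83.2 ± 5.16 and 166 ± 1.48 CPM. Rad21-TEV cells thus held less Rad21 mRNA than wild-type cells under OHT, by a log2 fold change of -1.15 unstimulated (SE 0.07, adjusted p = 4.24e-09), and the difference was called with LPS as well (adjusted p = 1.49e-08). The ethanol arm was also lower than wild-type cells, by -1.09 unstimulated and -0.75 with LPS. OHT against ethanol gave -0.06 unstimulated (SE 0.07, adjusted p = 0.823); with LPS Rad21 fell by 0.24 (SE 0.07, adjusted p = 0.0275). The call with LPS was lost without ethanol library 1 or OHT library 2 (highest adjusted p = 0.149), without the male libraries (0.151) or with total counts alone (0.103). The mRNA does not measure cleavage of the protein.

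**Figure D1:**
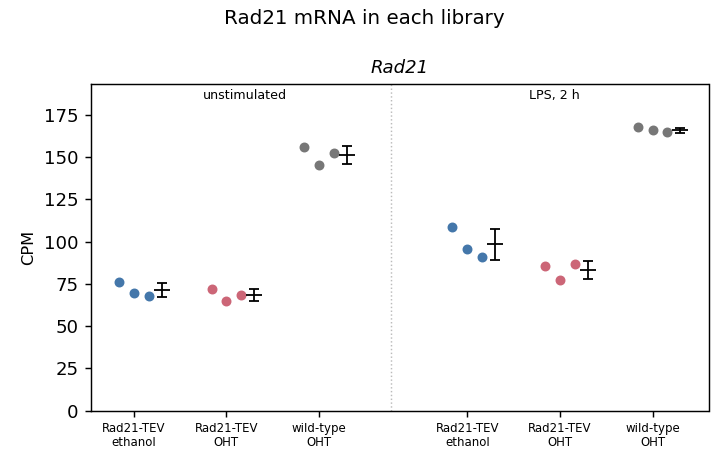
Rad21 mRNA in CPM (linear axis from 0) in each of the 18 libraries by genotype, drug and stimulation; coloured points are libraries and black marks the mean with its SD over 3. All 6 wild-type libraries lie above all 12 Rad21-TEV libraries, with group means of 151 and 166 CPM against 68.3 to 98.5 CPM.

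The first comparison sets OHT, which activates the protease, against ethanol in resting Rad21-TEV macrophages. An effect of the drug itself cannot be told apart from that of cleavage here. Mertk, a receptor for the uptake of apoptotic cells, fell from 52.4 ± 5.10 to 6.58 ± 0.508 CPM (SD, n = 3), a log2 fold change of -2.99 (SE 0.11, adjusted p = 3e-10). Slc40a1, the iron exporter ferroportin, fell from 83.2 ± 17.3 to 9.30 ± 1.39 CPM (-3.16, SE 0.18, adjusted p = 1.94e-08), and Plk2, a polo-like kinase gene, fell by 2.92 (SE 0.12, adjusted p = 3.21e-10). Myc, a transcription factor for growth, fell from 33.9 ± 3.66 to 8.07 ± 1.68 CPM (-2.07, SE 0.13, adjusted p = 3.22e-08). Among genes that rose, Egr3, an immediate early transcription factor, went from 2.47 ± 0.341 to 9.78 ± 1.34 CPM (1.99, SE 0.21, adjusted p = 1.6e-05). Il1b, the inflammatory cytokine interleukin-1 beta, rose from 11.1 ± 1.68 to 32.1 ± 6.43 CPM (1.54, SE 0.15, adjusted p = 8.37e-06), and the chemokine gene Ccl3 from 321 ± 31.4 to 746 ± 31.8 CPM (1.22, SE 0.12, adjusted p = 5.59e-06). Further genes with large falls were Prdm1 (-3.03), which encodes the transcriptional repressor Blimp-1, Thbs1 (-2.55), Dtx4 (-2.51) and the adrenergic receptor gene Adra1a (-2.44), while the adrenomedullin gene Adm (1.61), Nr4a3 (1.46) and Cd69 (1.23) rose. By edgeR's test 747 of 15936 genes were called, 188 higher and 559 lower, and 18 and 155 of these changed at least 2-fold. The paired fit called 1398 (442 higher and 956 lower), which held all 747, and without OHT library 3 the count was 491 (94 higher). Without ethanol library 1 or 2 the higher genes numbered 105 or 112, and total counts alone gave 260 higher and 486 lower.

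**Figure D2:**
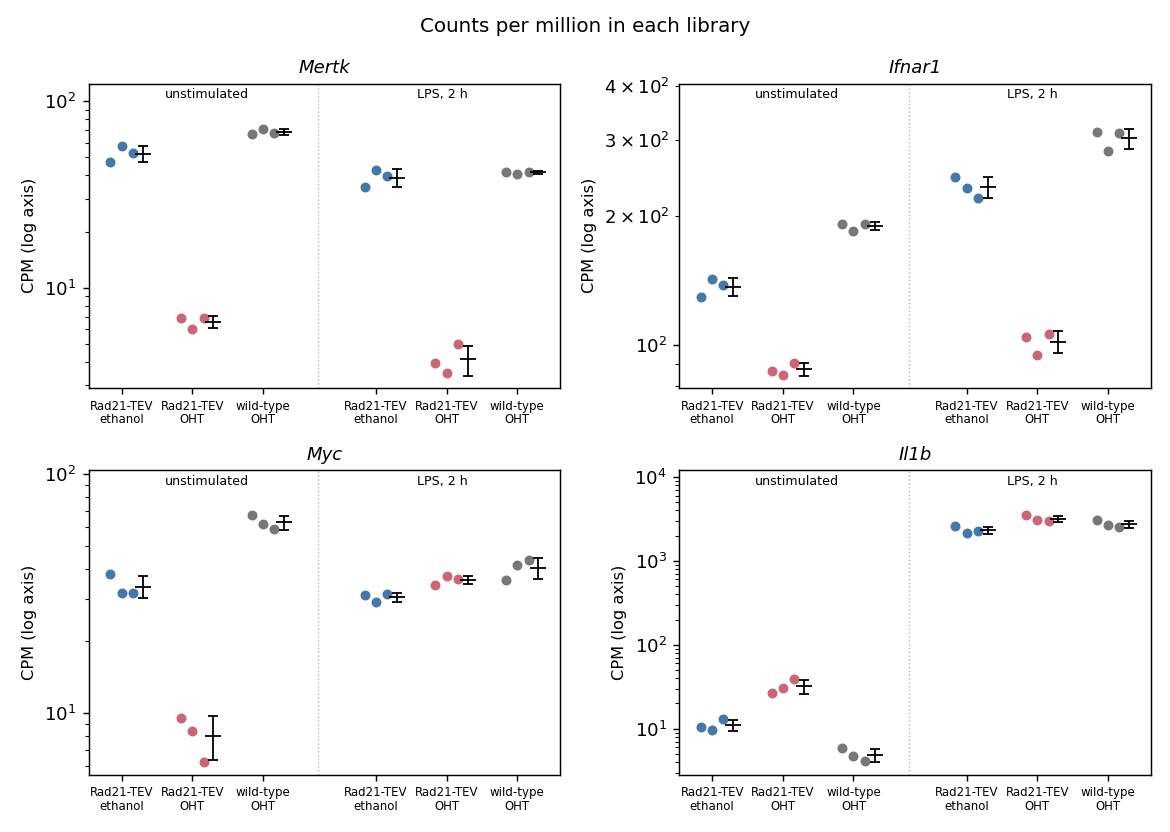
CPM (log axis) of Mertk, Ifnar1, Myc and Il1b in each library of the 6 groups; coloured points are libraries and black marks the mean with its SD over 3. Mertk averaged 52.4 CPM with ethanol and 6.58 CPM with OHT in unstimulated Rad21-TEV cells, and Il1b averaged 11.1 and 32.1 CPM there.

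Genes needed for S phase fell together in resting cells given OHT. Of 18 measured members 12 fell and none rose (16 and 0 adjusted over the list alone), including Cdc6 (-1.59), which loads the replicative helicase, the cyclin gene Ccne2 (-1.57), Uhrf1 (-1.51), a factor for maintenance of DNA methylation, and the helicase subunit gene Mcm5 (-1.04). Their median log2 fold change was -0.77 (camera adjusted p = 8.64e-19; adjusted p = 0.175 with an estimated correlation). Among the 20 G2/M genes none was called by edgeR, 3 were lower at an unadjusted p under 0.05, and DESeq2 called 0; the median was -0.11 (adjusted p = 0.394) and turned to 0.10 without ethanol library 1 (adjusted p = 0.0264). Without OHT library 1 or ethanol library 2 the G2/M median was -0.23 (adjusted p = 0.0409) or -0.27 (adjusted p = 5.24e-04).

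Some inflammatory genes of the early LPS response were higher with OHT without any LPS, and fewer were lower. Of 33 early primary response genes 11 rose, among them Il1b and Ccl3, and 5 fell, namely Atf3 (-1.15), a stress-induced transcription factor, Gadd45b (-0.85), Ptgs2, Fos and Dusp1; adjusted over the list alone 16 rose and 8 fell. The median was 0.35 (adjusted p = 0.000483; adjusted p = 0.323 with an estimated correlation), and 0.23 without OHT library 3 (adjusted p = 0.00347). Immediate early genes went both ways, with 2 higher (Egr3 and Ier2) and 6 lower, including Myc and Egr2 (-1.41); 4 and 6 passed when adjusted over the list alone, and the list's median was -0.17 (adjusted p = 0.151). Of 21 secondary response genes the chemokine gene Ccl7 alone was called (-0.98; also 1 adjusted over the list alone), with a list median of -0.07 (adjusted p = 0.466).

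Some regulators of macrophage identity and of interferon signalling were lower, and Tlr4 was higher. In the macrophage identity list 6 of 27 members fell and none rose (7 and 0 adjusted over the list alone), among them Mertk and the transcription factor genes Cebpb (-1.51) and Cebpa (-1.21). The median of the list was -0.11 (adjusted p = 0.00127; adjusted p = 0.175 with an estimated correlation), and -0.07 without OHT library 2 or ethanol library 3 (adjusted p = 0.00648 and 0.0255). Ifnar1, a chain of the type I interferon receptor, fell from 136 ± 6.63 to 87.6 ± 2.84 CPM (-0.64, SE 0.06, adjusted p = 5.59e-06), and Irf8 (-0.43) and the antiviral adaptor gene Mavs (-0.36) fell, whereas Tlr4, the LPS receptor, rose (0.52). These 4 were the called members of 18 type I interferon pathway genes (2 higher and 3 lower adjusted over the list alone); the median was 0.02 and the mean 0.03, while the test pointed lower (adjusted p = 0.872). Among 50 interferon-stimulated genes only Ifit1, an antiviral RNA-binding protein, was called (-0.95, adjusted p = 0.0422; none adjusted over the list alone), with a median of -0.26 (adjusted p = 0.0324; adjusted p = 0.885 with an estimated correlation). Among same-numbered libraries the medians were 0.18, -0.12 and -0.67. Without ethanol library 3 the list median was 0.09 (adjusted p = 0.295), without ethanol library 1 it was -0.46 (adjusted p = 6.67e-09), and the list call was also lost without OHT library 1 (adjusted p = 0.0843), OHT library 2 (0.0905) or the male libraries (0.0659). The calls of Ifit1 and Mavs were each lost without any library except ethanol library 1 (highest adjusted p = 0.286 and 0.177), and without the male libraries (0.15 and 0.149). Their fold changes without the male libraries were -1.04 and -0.34.

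The remaining lists had few called members in resting cells in the unpaired fit. Sqle, an enzyme of cholesterol synthesis, was the only called one of 23 sterol genes (-0.47; 2 lower adjusted over the list alone), and the median was -0.18 (adjusted p = 0.00815; adjusted p = 0.746 with an estimated correlation). The paired fit called 10 sterol genes lower (adjusted p = 4.61e-08; 0.149 with an estimated correlation), and the unpaired list call was lost without ethanol library 1 (adjusted p = 0.286) or OHT library 2 (adjusted p = 0.352), while the median was -0.30 without OHT library 1 (adjusted p = 1.96e-05). Of 9 LXR targets the cholesterol exporter gene Abca1 fell (-1.48, SE 0.18, adjusted p = 6.73e-05; also 1 adjusted over the list alone), and the list had an adjusted p of 0.255 unpaired and 0.0143 paired (0.358 with an estimated correlation). Among 16 cohesin genes the subunit gene Stag1 rose (0.22) while Cdca5 (-0.70), the gene of sororin, and Smc3 (-0.30) fell (3 higher and 6 lower adjusted over the list alone; list adjusted p = 0.384). Of 19 p53 targets Pmaip1, which encodes the pro-apoptotic Noxa, rose (0.57) and Plk2 fell (also 1 and 1 adjusted over the list alone); their median was 0.12, the mean -0.05 and the test pointed higher (adjusted p = 0.242). Dnaja1 rose among 10 heat shock genes (0.21; 1 higher adjusted over the list alone; list adjusted p = 0.446). Asns (0.35) and Herpud1 (0.45) rose among 12 unfolded protein response genes (3 higher and 1 lower adjusted over the list alone; list adjusted p = 0.0799 unpaired and 0.0295 paired, 0.36 with an estimated correlation). Of 14 glycolysis and hypoxia genes the oxidase gene Ero1l rose (0.21) and the hexokinase gene Hk2 fell (-0.58; 1 and 1 adjusted over the list alone; list adjusted p = 0.843).

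Several of these single calls in resting cells were lost when 1 library was left out. Those of Stag1 and Smc3 were lost without any library except OHT library 1 and ethanol library 2 respectively (highest adjusted p = 0.159 and 0.234), and that of Cdca5 without OHT library 3 or ethanol library 1 (0.0718). The call of Herpud1 was lost without any library except ethanol library 1 (highest adjusted p = 0.187), and that of Asns without OHT library 1 or 3 or ethanol library 2 or 3 (0.131). Dnaja1 and Ero1l lost theirs without OHT library 2 or 3 or ethanol library 1 (highest adjusted p = 0.098 and 0.101), and Sqle without ethanol library 1 (0.0505). Without the male libraries the calls of Stag1, Herpud1, Asns, Dnaja1 and Ero1l were lost (highest adjusted p = 0.174). Their fold changes in that fit were 0.2, 0.37, 0.36, 0.22 and 0.21. With total counts alone the calls of Smc3 (adjusted p = 0.096) and Herpud1 (0.0513) were lost.

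Markers of other cell types were not called in this comparison. By edgeR none of 13 neutrophil, 13 erythroid, 4 mast cell and progenitor, 11 hepatocyte, 8 dendritic cell, 11 stromal and 4 lymphoid markers passed, over all genes or adjusted over the list alone, and DESeq2 called 0. At an unadjusted p under 0.05, 1 neutrophil, 1 dendritic cell and 1 stromal marker were lower. The list tests gave adjusted p = 0.571, 0.566, 0.843, 0.242, 0.96, 0.573 and 0.798 in that order.

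The same drug comparison after 2 h of LPS asks how OHT changed stimulated Rad21-TEV cells. Mertk was again far lower with OHT, at 4.14 ± 0.754 against 39.0 ± 4.24 CPM (SD, n = 3; log2 fold change -3.24, SE 0.12, adjusted p = 6.88e-11). Bcl2l11, which encodes the pro-apoptotic protein Bim, was at 41.4 ± 13.8 against 365 ± 51.5 CPM (-3.15, SE 0.19, adjusted p = 1.86e-08), and Ifnar1 at 102 ± 6.08 against 233 ± 13.3 CPM (-1.20, SE 0.06, adjusted p = 3.53e-09). Genes with the largest falls also included Ch25h (-4.02), the cholesterol 25-hydroxylase, Icosl (-3.49), a ligand for T cell costimulation, Prdm1 (-3.44), Flrt3 (-3.59) and the pseudokinase gene Trib1 (-3.00). In the other direction Csf2, the cytokine GM-CSF, was at 32.8 ± 12.8 against 9.27 ± 2.15 CPM (1.82, SE 0.29, adjusted p = 0.00124). Il12b, a subunit of interleukin 12, was at 131 ± 18.2 against 67.9 ± 7.54 CPM (0.94, SE 0.11, adjusted p = 3.29e-05), and Ifitm1, an antiviral membrane protein, rose by 2.19 (SE 0.24, adjusted p = 1.2e-05). Tnfsf18 (2.13), Egr3 (1.90), P2ry13 (1.93) and Mreg (1.88) rose too. By edgeR 1984 genes were called, 675 higher and 1309 lower, with 107 and 261 of them changed at least 2-fold; scaling by total counts alone gave 897 higher and 1070 lower. The paired fit called 3094 (1189 higher and 1905 lower), with 1981 of the 1984 among them. The count was 2361 without OHT library 3, 1412 without ethanol library 1 (431 higher), 1214 without ethanol library 2 (327 higher), 1183 without the male libraries and 663 with only these 2 groups in the fit.

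Of the genes called in resting cells, 118 of 188 higher and 441 of 559 lower were called in the same direction with LPS, against 7.96 and 45.9 from independent lists; 3 and 8 went the opposite way. These comparisons share no libraries, but same-numbered libraries of both states deviated together, so they are not independent.

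The fall of S phase genes was present with LPS too. 13 of 18 members were lower and none higher (16 and 0 adjusted over the list alone), with Ccne2 at -1.91, Uhrf1 at -1.66 and the helicase subunit gene Mcm6 at -1.27, and a median of -0.65 (adjusted p = 1.15e-11; adjusted p = 0.479 with an estimated correlation). Of 20 G2/M genes Ccnb2 rose (0.49) and Top2a (-0.60) and Kif11 (-0.48) fell (1 and 2 adjusted over the list alone; list median -0.14, adjusted p = 0.422). Cohesin genes were lower, 7 of 16 (also 7 adjusted over the list alone), among them Cdca5 (-0.80), the cohesin regulators Pds5b (-0.39) and Pds5a (-0.35), and the subunit gene Smc1a (-0.30), with a median of -0.19 (adjusted p = 0.0436; adjusted p = 0.479 with an estimated correlation). This list call was lost in the paired fit (adjusted p = 0.0512), with total counts alone (0.0567), without ethanol library 1 (0.0599) or without OHT library 2 (0.0703). The calls of Ccnb2, Top2a, Kif11 and Pds5b were each lost without any of 3 or 4 single libraries, ethanol library 1 and OHT library 1 among them for each (highest adjusted p = 0.128, 0.109, 0.150 and 0.0705). Without the male libraries those of Ccnb2, Top2a, Kif11 and Pds5a were lost (highest adjusted p = 0.105), and with total counts alone that of Kif11 (0.0668). The fold changes without the male libraries were 0.38, -0.62, -0.55 and -0.24 for Ccnb2, Top2a, Kif11 and Pds5a.

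LPS response genes went both ways with OHT. Among 33 early primary response genes 7 were higher, including Ier3 (1.17) and Atf3 (0.71), and 4 lower, namely Ptgs2 (-1.35), which encodes the inducible cyclooxygenase, Sod2 (-0.39), Fos and Gadd45b; adjusted over the list alone 7 and 5 passed. Their median was -0.00 and their mean 0.01, and the test pointed higher (adjusted p = 0.633). Of 21 secondary response genes 3 were higher, Csf2, Il12b and Ebi3, and 5 lower, Edn1 (-2.56), the endothelin gene, Ccl7 (-1.44), Nos2, Saa3 and Marco; 3 and 6 passed adjusted over the list alone, and the median was -0.11 (adjusted p = 0.599). Immediate early genes were higher in 5 and lower in 2 of 14 cases, Jun (1.03), Egr3, Atf3, Nr4a1 and Klf4 against Fos and Egr2 (-2.48) (8 and 4 adjusted over the list alone), with a median of 0.38 (adjusted p = 0.0455; adjusted p = 0.582 with an estimated correlation). Their list call was lost in the paired fit (adjusted p = 0.0512), with total counts alone (0.0567), without the male libraries (0.0964), and without ethanol library 1 (0.111), OHT library 2 (0.141) or OHT library 3 (0.0849).

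Interferon genes showed lower receptors and some higher targets. Ifnar1, Ifnar2 (-0.49), the adaptor gene Ticam1 (-0.55), Irf8 and Mavs were the 5 lower and Tlr4 (0.48), Ifnb1, Ticam2 and Tmem173 the 4 higher members of the 18 type I interferon pathway genes (5 and 5 adjusted over the list alone; list median 0.12, adjusted p = 0.84). Of 50 interferon-stimulated genes Usp18 (1.14), a negative regulator of interferon signalling, and Ifih1 (0.71), an RNA sensor, rose, also when adjusted over the list alone, but the call of Usp18 was lost without OHT library 1 or ethanol library 2 or 3 (highest adjusted p = 0.113) or without the male libraries (0.152). The median was 0.21 (adjusted p = 0.0455; adjusted p = 0.894 with an estimated correlation), and the paired fit called 7 higher and 1 lower with a list adjusted p of 0.0682. The list call was also lost with total counts alone (adjusted p = 0.0567) and without the male libraries (0.0964), OHT library 1 (0.507), ethanol library 2 (0.23) or ethanol library 3 (0.251), and the median was 0.44 without ethanol library 1 (adjusted p = 5.13e-05).

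Macrophage identity genes were lower in 5 of 27 cases and higher in none, with Mertk, Cebpb (-2.46), the chemokine receptor gene Cx3cr1 (-1.86), the scavenger receptor gene Msr1 (-0.41) and Cd14 being the members (1 higher and 7 lower adjusted over the list alone; list median -0.04, adjusted p = 0.0569). Of 19 p53 targets 4 rose, Fas (1.40), Gdf15 (1.11), Pmaip1 (0.66) and Polk, and Plk2 fell (-1.60; 5 and 1 adjusted over the list alone; list adjusted p = 0.0564). Hif1a, the oxygen-regulated transcription factor, fell from 221 ± 9.35 to 137 ± 8.49 CPM (-0.69, SE 0.06, adjusted p = 7.35e-07), and Pfkfb3, a driver of glycolysis, fell by 1.03. With Bnip3, which rose (0.34), these were the called ones of 14 glycolysis and hypoxia genes (1 higher and 2 lower adjusted over the list alone; list adjusted p = 0.308). Dnajb9, Sdf2l1 and Asns rose among 12 unfolded protein response genes (0.19, 0.27 and 0.31; 3 adjusted over the list alone; list adjusted p = 0.0569). The heat shock genes Hspa1a and Hspa1b both fell (-1.06 and -1.06; 2 of 10 adjusted over the list alone; list adjusted p = 0.367), but these near-identical paralogs cannot be counted apart with certainty. Abca1 (-1.50) and Sqle (-0.33) were the called LXR target and sterol gene (1 and 0 adjusted over the list alone; both lists adjusted p = 0.633). The calls of Bnip3, Dnajb9, Sdf2l1, Asns and Sqle were each lost without any of 3 to 5 single libraries, ethanol library 1 among them for each (highest adjusted p = 0.108, 0.181, 0.162, 0.126 and 0.168). They were also lost without the male libraries (highest adjusted p = 0.287), and that of Sqle with total counts alone (0.0903).

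Among markers of other cell types with LPS, edgeR called the neutrophil marker Gfi1 lower (4 against 33 counts), while DESeq2 called 0 neutrophil markers. The MHC class II chaperone gene Cd74 was higher (0.97), and edgeR called none of the erythroid, mast cell, hepatocyte, stromal and lymphoid markers. DESeq2 called 0 of these as well, and at an unadjusted p under 0.05 1 hepatocyte marker was higher. Medians of erythroid (0.57) and hepatocyte markers (0.57) had adjusted p = 0.0569 each, those of neutrophil (0.43) and dendritic cell markers (0.28) 0.433 and 0.529.

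**Figure D3:**
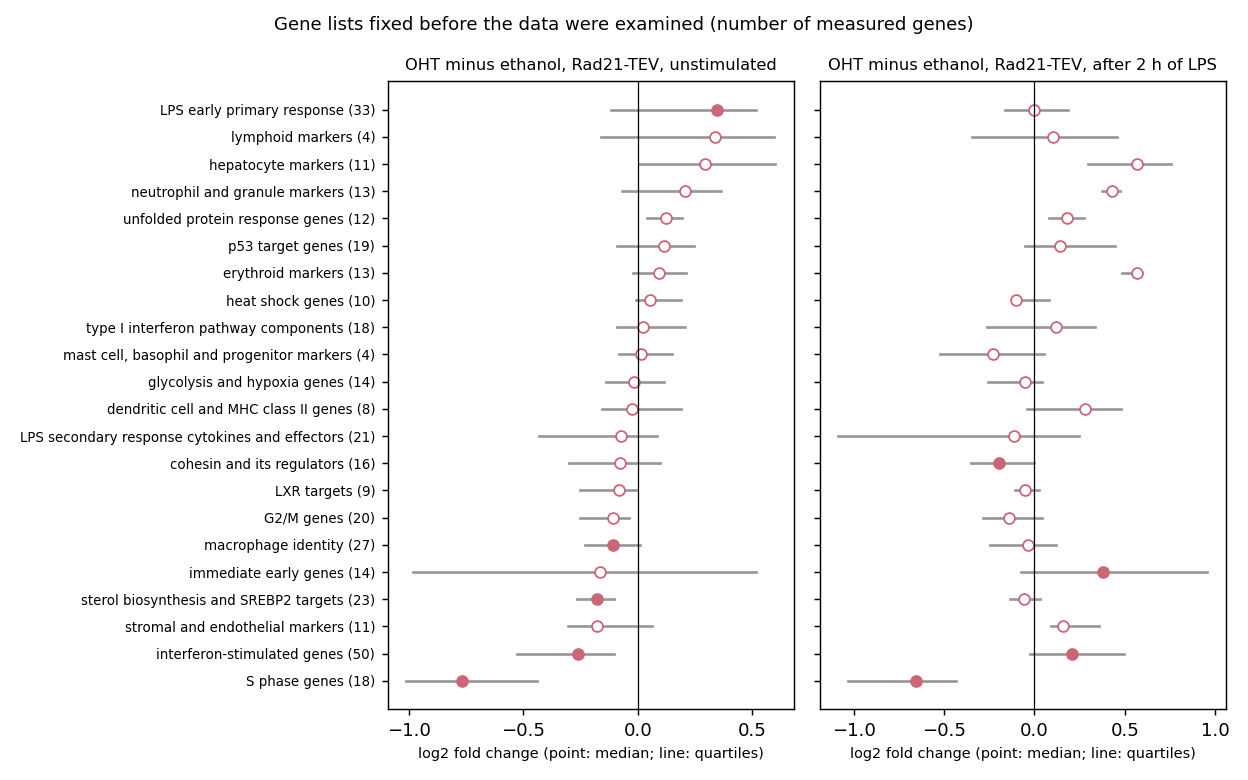
Median log2 fold change with OHT against ethanol (points) and quartiles (lines) of the 22 fixed gene lists in Rad21-TEV macrophages, unstimulated on the left and with LPS on the right. Filled points have a camera adjusted p under 0.05 at the preset correlation; S phase genes lie at -0.77 and -0.65.

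The next comparisons give the LPS response itself in each arm. Tnf, the cytokine tumour necrosis factor, rose by 6.07 on the log2 scale in Rad21-TEV cells with ethanol (SE 0.12, adjusted p = 2.59e-15), 6.00 with OHT (SE 0.12, adjusted p = 2.16e-15) and 6.69 in wild-type cells (SE 0.12, adjusted p = 6.41e-16). It reached 2688 ± 68.4, 2699 ± 340.3 and 3910.0 ± 58.6 CPM (SD, n = 3). Nfkbiz, a cofactor of NF-kappaB, rose by 6.27, 6.36 and 7.53 in that order, the interferon-induced chemokine gene Cxcl10 by 7.28, 8.23 and 7.05, and Nos2, the inducible nitric oxide synthase, by 9.39, 9.09 and 9.81. Il23a had no counts in any unstimulated group and was at least 936-fold, 1082-fold and 1081-fold higher, against a floor of 3 counts over the group. Csf2 was at least 1478-fold higher with OHT in Rad21-TEV cells and at least 1151-fold in wild-type cells on the same floor, and its ratio with ethanol was 708 (95% counting interval 196 to 5853). Ifnb1, the gene of interferon beta, had a ratio of 1075 (367 to 5214) with ethanol and rose by 10.87 and 9.36 in the other two arms. Genes that fell in each arm included Cebpa (-1.85, -1.23 and -1.76), Ier5l (-3.32, -3.33 and -3.77) and Irf8 (-1.43, -1.31 and -1.14). By edgeR LPS changed 4970 genes with ethanol (2544 higher and 2426 lower), 5255 with OHT (2604 and 2651) and 4611 in wild-type cells (2119 and 2492). Scaling by total counts alone shifted the median of all genes by -0.19, -0.19 and -0.20, with 1727 higher and 5192 lower, 1630 and 5208, and 1435 and 5759, and the fold changes here are relative to that median.

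Early primary response genes rose together in each arm. In each arm 31 of 33 rose and Egr1 and Fos fell (the same counts adjusted over the list alone), with medians of 3.11 with ethanol, 3.03 with OHT and 3.64 in wild-type cells (adjusted p = 1.45e-35, 4.39e-35 and 3.02e-46; with an estimated correlation 0.000157, 0.000168 and 4.11e-05). Secondary response genes rose in 20, 19 and 21 of 21 cases (adjusted over the list alone 20, 19 and 21), with medians of 4.19, 4.64 and 5.29 (adjusted p = 8.86e-20, 2.18e-17 and 2.31e-24; with an estimated correlation 0.000115, 0.000168 and 3.8e-05). Interferon-stimulated genes rose in 25, 36 and 23 of 50 cases (27, 39 and 24 adjusted over the list alone), led by Ccl5, Gbp5 and Cxcl10, with medians of 0.73, 1.16 and 0.67 (adjusted p = 1e-09, 1.98e-15 and 2.16e-09; adjusted p = 0.598, 0.428 and 0.545 with an estimated correlation). Without unstimulated library 3 the ethanol arm had 35 rises and a median of 1.18 (adjusted p = 9.31e-17). Type I interferon pathway genes gave 12, 13 and 12 rises with falls of Irf8, Tlr4 and Mavs in each (adjusted p = 0.00134, 0.00182 and 0.00124; adjusted p = 0.435, 0.428 and 0.303 with an estimated correlation). Heat shock genes with rises were Hspa1a, Hspa1b, Hsp90aa1, Hspa8 and Dnaja1 in each arm (adjusted p = 0.00105, 0.00434 and 0.00212; adjusted p = 0.0503, 0.102 and 0.0742 with an estimated correlation). Of the genes called in Rad21-TEV cells with ethanol, 1830 higher and 1837 lower ones were called in wild-type cells in the same direction, against 338 and 379 from independent lists, with 4 and 1 in the opposite direction.

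Whether OHT changed the LPS response of Rad21-TEV cells was tested as the difference of the 2 responses. A response is called higher where this difference lies above 0 and lower where it lies below, so a weaker fall counts as higher. Adm rose from 1.38 to 38.6 CPM with ethanol but from 4.19 to 10.8 CPM with OHT, a difference of -3.44 on the log2 scale (SE 0.40, adjusted p = 0.000217). Jdp2, a repressor of AP-1 sites, rose from 5.32 to 60.0 CPM with ethanol and from 7.50 to 11.7 CPM with OHT (-2.87, SE 0.23, adjusted p = 5.1e-06), and Ptch1, the Hedgehog receptor, from 10.2 to 49.2 and from 11.1 to 13.1 CPM (-2.04, SE 0.19, adjusted p = 1.88e-05). Hif1a rose from 117 to 221 CPM with ethanol and stood at 124 and 137 CPM with OHT (-0.77, SE 0.08, adjusted p = 9.29e-05). Il1b started higher with OHT and ended at 3180.0 against 2325 CPM, so its response was lower by a log2 difference of -1.09 (SE 0.21, adjusted p = 0.0161). The response of Myc was higher with OHT, from 8.07 to 36.2 CPM against 33.9 to 30.6 CPM with ethanol (2.31, SE 0.17, adjusted p = 5.1e-06), as were those of Atf3 (1.86, SE 0.15, adjusted p = 5.1e-06) and Cd274, the checkpoint ligand PD-L1 (1.99, SE 0.27, adjusted p = 8e-04). Lower responses were also called for Rgs3 (-1.96), Ccl3 (-0.83) and Ifnar1 (-0.56), and higher ones for Ifitm1 (1.82) and Jun (1.41). In total 149 genes had a called difference, 48 higher and 101 lower. The paired fit called 309 (112 and 197), of which 148 were among the 149, and the count was 90 without OHT library 3 of the unstimulated cells or without ethanol library 2 of the LPS-treated cells, 98 without ethanol library 3 of the unstimulated cells, and 68 without the male libraries. The calls of Il1b and Ccl3 were lost without ethanol library 2 of the unstimulated cells, among others (highest adjusted p = 0.0595 and 0.058), and without the male libraries (0.177 and 0.0917), as was that of Ifitm1 (0.173). Without the male libraries the differences of Il1b, Ccl3 and Ifitm1 were -1.07, -0.88 and 1.77.

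By list, interferon-stimulated genes had a median difference of 0.48 in their LPS response between OHT and ethanol (adjusted p = 1.59e-06; adjusted p = 0.888 with an estimated correlation). Among same-numbered libraries the medians were -0.08, 0.30 and 0.87. Only Ifit1 was called of 50 (1.62; also 1 adjusted over the list alone; lost without any of 10 single libraries, highest adjusted p = 0.12, or without the male libraries, 0.377). Without ethanol library 3 of the unstimulated cells the list median was 0.13 (adjusted p = 0.0664), and without OHT library 1 of the LPS-treated cells 0.28 (0.0111). Of 33 early primary response genes Ccl3, Nfkbia, Il1b and Icam1 had lower and Atf3 and Gadd45b higher responses (8 lower and 3 higher adjusted over the list alone). Their median was -0.20 (adjusted p = 0.00806; adjusted p = 0.533 with an estimated correlation; 0.11 without OHT library 1 of the LPS-treated cells). Immediate early genes had 3 higher responses, Myc, Atf3 and Jun, and none lower (4 and 1 adjusted over the list alone; median 0.16, adjusted p = 0.00186; adjusted p = 0.533 with an estimated correlation). With single libraries left out that median ran from 0.04, without ethanol library 1 of the LPS-treated cells (adjusted p = 0.0234), to 0.39, without OHT library 1 of those cells (0.000172). Cohesin genes, p53 targets (with higher responses of Fas and Plk2, 1.16 and 1.33) and heat shock genes (with a lower one of Hspa1a, -1.41) each had an adjusted p of 0.049, with 0.533 under an estimated correlation. Each of these calls was lost when any of 7 or 8 of the 12 libraries was left out (highest adjusted p = 0.202, 0.26 and 0.26) and with total counts alone (0.0588 each). Those of cohesin genes and p53 targets were also lost without the male libraries (adjusted p = 0.0735 and 0.15). The call of Fas itself was lost without ethanol library 1 or 3 of the unstimulated cells (0.0531), and that of Hspa1a without any of 5 libraries (0.0934) or without the male libraries (0.281). Sterol genes had an adjusted p of 0.0686 unpaired and 0.00015 in the paired fit (0.402 with an estimated correlation). For S phase genes edgeR and DESeq2 called none of 18, with 0 at an unadjusted p under 0.05 (median -0.01, adjusted p = 0.991). For secondary response genes both called none of 21, with 3 higher and 2 lower responses at an unadjusted p under 0.05 (median -0.20, adjusted p = 0.884).

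The genes that LPS induced at least 2-fold in wild-type cells formed a list of 909 chosen on the contrast of the wild-type groups, in the fit over all 18 libraries. In resting Rad21-TEV cells OHT raised 46 and lowered 82 of them, against 188 and 559 of all 15936 genes tested. The median of the list was 0.00 (camera p = 0.831, and p = 0.898 with an estimated correlation). Over the 899 genes with counts in these groups it was 0.003. After LPS 95 of the 909 were higher and 193 lower with OHT, against 675 and 1309 of all genes tested. The median of the list was then -0.10 (camera p = 0.00654, and p = 0.121 with an estimated correlation). That median was -0.04 without ethanol library 1 and -0.06 without OHT library 2, and among same-numbered libraries -0.16, -0.17 and 0.01. The LPS response of the list differed by a median of -0.12 between OHT and ethanol (camera p = 6.62e-04; p = 0.0585 with an estimated correlation), with 17 higher and 55 lower responses, and by the same -0.12 without the 47 genes that had 3 or fewer counts in a group. Among same-numbered libraries the median difference in response was -0.18, -0.14 and -0.04, and over all libraries but OHT library 2 of the LPS-treated cells the list's median was -0.08. Even so, 807 of the 909 were called higher with LPS in Rad21-TEV cells with ethanol and 758 with OHT, with 0 and 5 called lower and medians of 1.92 and 1.81. For the 527 genes that LPS lowered at least 2-fold in wild-type cells, OHT raised 8 and lowered 30 at rest, 32 were higher and 35 lower after LPS, and 8 had a higher and 0 a lower response (median 0.05, camera p = 0.0337; p = 0.226 with an estimated correlation).

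Rad21-TEV cells were next set against wild-type cells with the same drug. In unstimulated cells the transmembrane protein gene Tmem51 was higher at 54.5 ± 4.65 against 1.67 ± 0.280 CPM (SD, n = 3; log2 fold change 5.03, SE 0.19, adjusted p = 2.95e-11), and Tnfsf18 (4.99) and the serpin gene Serpinb2 (4.06) were higher too. Dll1, a Notch ligand (-5.30), the neurotrophic factor gene Gdnf (-4.98), Sncaip (-5.30), Cx3cr1 (-3.44), Mertk (-3.38) and Myc (-2.96) were lower. With LPS the largest falls included Icosl (-5.67), the chemokine gene Cxcl3 (-5.48), Ch25h (-4.97) and Ccl7 (-3.76), while Tnfsf18 (6.11), Ifih1 (1.93) and Usp18 (1.95) were higher. By edgeR 6411 genes differed without LPS (3187 higher and 3224 lower in Rad21-TEV cells) and 6864 with LPS (3670 and 3194).

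The 2 control arms differed from each other almost as widely, although in the ethanol arm no OHT was given. Tmem51 was at 30.6 ± 2.96 CPM in unstimulated Rad21-TEV cells with ethanol against 1.67 ± 0.280 CPM in wild-type cells with OHT (4.20, SE 0.18, adjusted p = 1.54e-09), and Serpinb2 (4.97) was higher. Igfbp5, a binding protein of insulin-like growth factors (-4.06, SE 0.31, adjusted p = 1.68e-07), Serpine2 (-3.66), Dll1 (-3.32), Cx3cr1 (-2.07) and Myc (-0.89) were lower. With LPS the matrix protein gene Postn (3.13) and the interferon-induced Mx2 (1.83) were higher, while Ccl7 (-2.32), Zfp36, which destabilises cytokine mRNAs (-1.36, SE 0.08, adjusted p = 2.56e-08), and Tnf (-0.54, SE 0.09, adjusted p = 0.00032) were lower. In all 5098 genes were called unstimulated (2608 higher and 2490 lower) and 5303 with LPS (2964 and 2339). Genotype, embryo and drug all differ between these arms, as did the mitochondrial share of counts.

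Proliferation genes were lower in Rad21-TEV cells in all 4 of these comparisons. Both comparisons of a state use the same wild-type libraries, so the 4 are not independent. Of 18 S phase genes 18 were lower under OHT in both states and 17 with ethanol in both states (18 in each adjusted over the list alone). Their medians were -1.67 and -1.67 under OHT and -1.06 and -1.06 with ethanol, unstimulated and with LPS (adjusted p = 1.35e-14, 5.85e-15, 2.78e-11 and 8.59e-13; adjusted p = 0.263, 0.334, 0.361 and 0.208 with an estimated correlation). All 20 G2/M genes were lower in each, the mitotic kinase genes Plk1 (-1.85) and Aurka (-1.77) in the unstimulated control arms among them (also 20 adjusted over the list alone). The medians were -1.80, -1.59, -1.65 and -1.49 (adjusted p = 2.18e-16, 5.85e-15, 1.66e-20 and 4.58e-19; adjusted p = 0.263, 0.334, 0.234 and 0.208 with an estimated correlation).

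Early primary response genes were higher in unstimulated Rad21-TEV cells, 23 of 33 under OHT (Fos, Plaur, Gadd45b and Atf3 lower; median 0.85, adjusted p = 1.26e-07) and 21 with ethanol (Plaur lower; median 0.46, adjusted p = 9.63e-08). Adjusted over the list alone 23 and 22 were higher, and with an estimated correlation the adjusted p was 0.2 and 0.191. Icam1, an adhesion molecule, was at 285 CPM with OHT and 199 with ethanol against 91.0 CPM in wild-type cells, and Ccrl2, an atypical chemokine receptor, at 104 and 69.1 against 20.5 CPM. After LPS Icam1 reached 2389, 2389 and 2425 CPM and Ccrl2 1479, 1385 and 1448 CPM in the same order. In the stimulated state Traf1, Atf3, Nfkbie and Relb of the list were higher and 13 lower under OHT (adjusted p = 0.0587), and Relb was higher and 12 lower with ethanol (median -0.23, adjusted p = 0.0016; adjusted p = 0.259 with an estimated correlation).

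Interferon-stimulated genes were higher with LPS in Rad21-TEV cells, 22 of 50 under OHT with none lower (median 0.56, adjusted p = 0.00124; adjusted p = 0.679 with an estimated correlation). With ethanol 18 were higher, among them Ifih1 (1.22) and Ccl5 (1.10), and Oas3 was lower (median 0.49, adjusted p = 0.00972; adjusted p = 0.875 with an estimated correlation). Without ethanol library 1 the median was 0.25 with 6 higher (adjusted p = 0.167), and without wild-type library 3 or 1 the higher members numbered 8 or 11. Unstimulated, 7 were higher and Oas3 and Eif2ak2 lower under OHT (adjusted p = 0.72) and 9 higher with ethanol (adjusted p = 0.0379; adjusted p = 0.839 with an estimated correlation). The latter median was 0.40, and 0.01 without ethanol library 3 (adjusted p = 0.825), and its call was also lost without wild-type library 1 (0.202) or 3 (0.114). Unfolded protein response genes were lower in the LPS-treated control arms, 8 of 12 with Dnajb9 higher (adjusted p = 0.000471, and 0.208 with an estimated correlation). Chac1 (-2.87), Herpud1 (-1.17) and the asparagine synthetase gene Asns (-1.27) led them. The list was also called lower in the unstimulated control arms and under OHT with LPS, with medians of -0.27 and -0.31. Those list calls were lost with an estimated correlation (adjusted p = 0.4 and 0.367) and with total counts alone (0.0549 and 0.0626). In the LPS-treated control arms 8 of 14 immediate early genes were lower and none higher (adjusted p = 0.000305, and 0.208 with an estimated correlation). Alas2 and Hbb-b2, genes of haem and globin synthesis, were lower (-1.15 and -1.08), and each call was lost without ethanol library 1 or wild-type library 1 (highest adjusted p = 0.166 and 0.227). That of Alas2 was also lost without the male libraries (adjusted p = 0.0637), and that of Hbb-b2 without ethanol library 3 or wild-type library 3. The erythroid list had a median of -1.03 (adjusted p = 0.00667; adjusted p = 0.613 with an estimated correlation), and of -0.66 without wild-type library 1 (adjusted p = 0.0498).

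Genes that moved with OHT were set against those that separate OHT-treated Rad21-TEV from wild-type cells, which share the OHT-treated Rad21-TEV libraries. At rest 145 genes were higher and 505 lower in both, against 37.6 and 113 from independent lists, and 14 went the opposite way. Unchanged groups gave 0 shared calls at most in 20 simulations, which bears only on chance without any effect. With LPS 518 were higher and 1024 lower in both, against 155 and 262, and 61 went the opposite way. Across genes, which are not independent replicates, the fold changes correlated at 0.483 at rest, against 0.497 in the simulations, and at 0.569 with LPS, against 0.495, and the covariances were 0.177 and 0.257 against 0.0616 and 0.0607 simulated. Groups of 3 cannot be split into parts of at least 2 libraries, so part of the excess overlap may stem from the shared libraries.

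The LPS response differed between genotypes under OHT in 579 genes, 295 with a higher and 284 with a lower response in Rad21-TEV cells. Il1b rose from 4.87 to 2730.0 CPM in wild-type cells and from 32.1 to 3180.0 CPM in Rad21-TEV cells, a difference of -2.50 on the log2 scale (SE 0.21, adjusted p = 2.58e-06). Lower responses were also found for Adm (-5.07, SE 0.41, adjusted p = 1.67e-06), Ccrl2 (-2.31, SE 0.18, adjusted p = 1.16e-06), Icam1 (-1.67, SE 0.12, adjusted p = 3.98e-07) and the NF-kappaB inhibitor gene Nfkbie (-1.49, SE 0.12, adjusted p = 1.22e-06). Dusp6, a phosphatase for ERK kinases, fell from 348 to 15.4 CPM in wild-type cells but from 282 to 85.0 CPM in Rad21-TEV cells (2.77, SE 0.15, adjusted p = 3e-08), and Myc had a higher response (2.80, SE 0.17, adjusted p = 6.78e-08). Of 33 early primary response genes 23 had a lower response and Gadd45b and Atf3 a higher one (27 and 2 adjusted over the list alone), with a median difference of -1.17 (adjusted p = 3.93e-35; 0.000333 with an estimated correlation). Of 21 secondary response genes Ptges (-3.49), Saa3 (-2.30) and Ccl7 (-1.01) responded less and Ccl2 more (1.28; median -0.98, adjusted p = 0.0214; adjusted p = 0.33 with an estimated correlation). This list call was lost when any of 6 single libraries was left out (highest adjusted p = 0.233, without OHT library 1 of the LPS-treated Rad21-TEV cells), and the call of Ccl7 without OHT library 3 of the unstimulated ones (0.0502). Ifih1 (1.44) and Ifit1 (2.11) responded more among 50 interferon-stimulated genes (7 adjusted over the list alone; median 0.66, adjusted p = 1.28e-05; adjusted p = 0.869 with an estimated correlation). Without wild-type library 2 of the unstimulated cells that median was 0.42 (adjusted p = 0.0018). The paired fit called 964 genes (467 and 497), and without wild-type library 1 or 2 of the unstimulated cells 190 and 188 genes had a higher response.

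The same test between the 2 control arms was added after their levels had been seen to differ. It called 198 genes, 109 with a higher and 89 with a lower response in Rad21-TEV cells with ethanol, and the paired fit called 429 (234 and 195). The higher responses numbered 70 without wild-type library 1 of the unstimulated cells, and 71 without wild-type library 2 of the LPS-treated cells or ethanol library 2 of the unstimulated cells. Il1a, the cytokine interleukin-1 alpha, rose from 3.71 to 1886 CPM in wild-type cells and from 20.8 to 2002 CPM with ethanol in Rad21-TEV cells (-2.40, SE 0.26, adjusted p = 7.55e-05). Ccrl2 (-1.82, SE 0.18, adjusted p = 4.01e-05), Icam1 (-1.15, SE 0.12, adjusted p = 4.94e-05) and Nfkbie (-1.19) also responded less from higher unstimulated levels, whereas Zfp36 (-1.21, SE 0.12, adjusted p = 3.37e-05) rose from 68.5 to 217 CPM against 75.8 to 556 CPM in wild-type cells. Higher responses were called for Dll1 (3.35), for Dusp6, which fell less (1.91), and for the antisense gene Foxl2os (4.23), whose counts are uncertain without the strand setting. Of 33 early primary response genes 20 had a lower response and none a higher one (25 and 0 adjusted over the list alone), with a median of -0.87 (adjusted p = 1.94e-48; 6.45e-05 with an estimated correlation). Immediate early genes had 5 lower responses, Egr2, Ier2, Jun, Junb and Dusp1, and a higher one of Fosb (8 and 2 adjusted over the list alone; median -0.49, adjusted p = 2.22e-06; adjusted p = 0.0876 with an estimated correlation). Among secondary response genes Saa3 alone was called (-1.66), which was lost without any of 6 single libraries (highest adjusted p = 0.063). Their list had a median of -0.63 (adjusted p = 0.00186; adjusted p = 0.0876 with an estimated correlation), and of -0.96 without wild-type library 2 of the unstimulated cells (adjusted p = 0.000821).

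**Figure D4:**
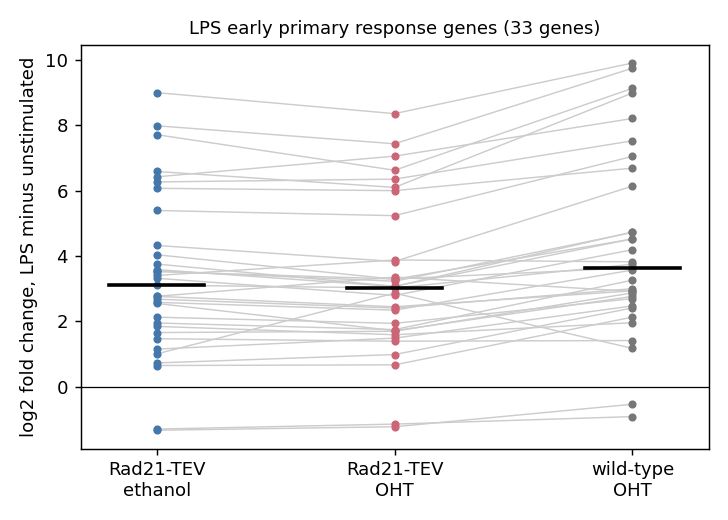
LPS response (log2 fold change, LPS against unstimulated) of the 33 early primary response genes in Rad21-TEV cells with ethanol or OHT and in wild-type cells with OHT; points are genes, grey lines join a gene across arms and black bars are medians. Medians were 3.11, 3.03 and 3.64.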

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

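The tests of the difference in LPS response were fixed before the data were examined, except that between the control arms. The other tests in this part were chosen after the result they bear on had been seen, except 3: that of the same-numbered differences of the S phase genes, that of the male libraries for the early primary response genes, and that of genes near Rad21. The LPS response differed between groups, by the test of the difference itself, in 149 genes between OHT and ethanol in Rad21-TEV cells, in 579 genes between Rad21-TEV and wild-type cells under OHT, and in 198 genes between the 2 control arms. Early primary response genes differed in LPS response by a median of -1.17 under OHT and of -0.87 between the control arms. Both differences use the same wild-type libraries.

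S phase genes were lower with OHT in unstimulated Rad21-TEV cells, with a median of -0.77 (adjusted p = 8.64e-19; adjusted p = 0.175 with an estimated correlation). The tables argue against scaling as the cause, since the median was -0.74 with total counts alone, and against 1 set of same-numbered libraries, since the 3 same-numbered medians were -0.55 at the highest. A smaller share of cells anywhere in the cycle would lower G2/M genes alike, but their same-numbered medians lay above those of the S phase genes by 0.532 or more. An effect of OHT without Rad21 cleavage cannot be told apart, because no wild-type cells were given ethanol, and S phase genes already differed between the control arms by a median of -1.06 together with genotype. The G2/M values thus argue against a smaller share of cycling cells as the whole cause, while a part of the fall from it stays open. Loss of Rad21 remains a candidate explanation, as a hypothesis, beside the drug.

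Early primary response genes responded less to LPS in Rad21-TEV than in wild-type cells. Between the control arms, where the Rad21-TEV cells were given no OHT, the median difference was still -0.87. The wild-type arm did receive OHT, so an effect of the drug on the response may enter this difference. Whether OHT-induced cleavage is the whole cause under OHT is thus not decided, and leakage of the protease without OHT stays open. The male libraries are not the source of the difference between the control arms, which was -0.86 without them. Part of the difference lies in higher unstimulated levels. LPS-treated levels also differed by a median of -0.23, with 3 members higher and 16 lower at an unadjusted p under 0.05. DESeq2 called 1 member higher and 14 lower there at an adjusted p under 0.05. For those 14 the lower LPS-treated level argues against a higher start as the whole cause. For the list as a whole this cannot be told apart. With an estimated correlation, neither the list difference with LPS (camera adjusted p = 0.259) nor the unstimulated one (0.191) passed. Genotype, embryo and drug differ between the control arms as well and were not tested apart.

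The 2 unstimulated control arms differed in 5098 genes. To look at DNA carried along with the Rad21 allele, genes within 10 Mb of Rad21 were counted, and they made up 0.412% of those called. In that window 21 of 53 tested genes were called, 39.6% against 32.0% elsewhere (odds ratio 1.40, two-sided Fisher's exact test p = 0.24). With 53 genes tested there, the share had to be small, so it covers only direct effects in that window. A longer stretch of carried DNA, or its effects on genes elsewhere, was not tested. Sex is argued against as the whole cause by the 4850 genes called without the male libraries. Genotype, embryo and the drug remain open and are confounded.

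For each of the 9 comparisons of 2 groups, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts were 747 and 1984 for OHT without and with LPS, where the highest other counts were 0 and 2. They were 4970, 5255 and 4611 for LPS in the 3 arms, 6411 and 6864 for genotype under OHT, and 5098 and 5303 for the control arms, each against a highest other count of 0. The same held for OHT and for LPS among the 4 splits that part as many same-numbered pairs.

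For the differences in LPS response, chance is not excluded by such counts. Of 100 drawn splits 7 gave as many genes as OHT against ethanol (149, highest other 2472), 11 as many as genotype under OHT (579, highest other 4328) and 9 as many as the control arms (198, highest other 7484). The high counts point to a structure of the samples: every other split as large lay nearer to the exchange of groups in 1 stimulation state only, which adds the 2 group effects up instead of taking their difference, and the highest split not nearer to that exchange gave 144, 213 and 48 genes. Among 18 drawn splits that part as many pairs for OHT against ethanol the highest was also 2472.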

How the results depend on the processing

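The comparison of the LPS response of the 2 control arms, the fits without the male libraries, and the paired fits of the genotype interactions, of the gene lists and of the LPS-induced lists were chosen after the data had been seen. The replicate numbers pair libraries within a genotype, and with the replicate block nested in genotype more genes were called: 1398 for OHT in unstimulated and 3094 in LPS-treated Rad21-TEV cells, 309 for the difference in LPS response between OHT and ethanol, 964 between genotypes under OHT and 429 between the control arms. A block by number over all 18 libraries gave 308 for the last. With only the compared groups in the fit, counts were lower for OHT with LPS (663), for LPS in Rad21-TEV cells with OHT (3261) and for the difference between OHT and ethanol (77). They were higher for LPS in wild-type cells (5814) and for the difference between the control arms (311). DESeq2 called 265 genes for the difference between OHT and ethanol and 354 for that between the control arms. Total counts alone called 7194 genes for LPS in wild-type cells. Without the male libraries, which leaves 2 libraries a group, 1183 genes were called for OHT with LPS and 68 for the difference between OHT and ethanol. The cause was not tested where the setting does not show it.

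With each library left out in turn, counts ran from 491 to 603 for OHT without LPS and from 1214 to 2361 with LPS. They ran from 4216 to 4587, 4279 to 5565 and 3798 to 3961 for LPS in Rad21-TEV cells with ethanol, with OHT and in wild-type cells. For genotype under OHT they were 5353 to 5763 unstimulated and 5955 to 6857 with LPS, and for the control arms 3996 to 4704 and 4302 to 4550. The differences in LPS response gave 90 to 179 for OHT against ethanol, 430 to 742 for genotype and 134 to 163 for the control arms. Medians of the wild-type LPS-induced list were 0.00 to 0.03, -0.14 to -0.04 and -0.15 to -0.08 for OHT without LPS, with LPS and for the difference in response.

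For that list the estimated correlation left the medians at -0.10 with LPS (p = 0.121) and -0.12 for the difference (p = 0.0585), or -0.10 (p = 0.24) and -0.12 in the paired fit, none past the threshold. The median of the glycolysis and hypoxia list with LPS in wild-type cells went from 0.09 (adjusted p = 0.00573) to -0.11 (adjusted p = 0.0327) with total counts alone, a shift like that of all genes (-0.20). Besides the lists named with their paired values among the results, the paired fit ended the list calls of dendritic cell genes with LPS under OHT in Rad21-TEV cells (0.0268 to 0.0546), of immediate early genes with LPS in wild-type cells (0.0459 to 0.0637) and of cohesin genes in the difference between OHT and ethanol (0.049 to 0.0547). It added those of S phase and sterol genes with LPS with ethanol (0.031 and 0.000137), of sterol genes in wild-type cells (0.00315), and of sterol and heat shock genes in the response of the control arms (0.0314 and 0.0399). With an estimated correlation these 5 had adjusted p = 0.969, 0.35, 0.45, 0.53 and 0.382 in that order. The block nested in genotype changed no other list call and ended no call of a gene named with its fold change. Of 210 such calls 180 held with every library left out in turn and 30 were lost with at least 1, with 0 changes of sign. Over the other settings 29 of 1209 values for named genes were no longer past the threshold and none turned. For the lists 128 of 350 were not, mostly with an estimated correlation. Depth set a floor of 0.0322 to 0.0722 CPM per library, under which a gene was not detectable.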

Other observations

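Of the tests in this part, those of gene span and of neighbouring genes were chosen before their results were seen. The test of LPS-induced genes, the matching on LPS-treated levels and the count without overlapping genes were chosen after.

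Some metabolic and cell cycle genes also moved with LPS. Hk2, the hexokinase gene of activated macrophages, and Ero1l were higher in each arm; 6 of 14 glycolysis and hypoxia genes rose in wild-type cells (adjusted p = 0.00573; adjusted p = 0.118 with an estimated correlation), against 4 with ethanol (Slc2a1, Hk2, Ero1l and Hif1a) and Hk2 and Ero1l with OHT in Rad21-TEV cells, where Pfkfb3 fell. The median in wild-type cells was 0.09, and -0.11 with total counts alone, a shift like that of all genes (-0.20). Cdc6 and Cdt1, which license replication origins, fell in each arm, with Mcm2 and Ccne1 in Rad21-TEV cells and Ccne2 with OHT. The S phase list was called lower with OHT in Rad21-TEV cells (median -0.24). That call was lost with an estimated correlation in camera (adjusted p = 0.786) and with total counts alone (0.0677). Mki67, a marker of cycling cells, rose by 1.48 with ethanol, 1.80 with OHT and 0.90 in wild-type cells, the only called G2/M gene in each. In the paired fit 13 of 23 sterol genes fell with LPS with ethanol and 14 in wild-type cells (adjusted p = 0.000137 and 0.00315; adjusted p = 0.35 and 0.45 with an estimated correlation), against 5 and 1 unpaired.

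Single markers of other cell types differed between the genotypes in both states. The comparisons under OHT and with ethanol share their wild-type libraries in each state and are not independent. Of 11 stromal and endothelial markers 2, 3, 2 and 1 were higher and 2, 1, 0 and 1 lower in Rad21-TEV cells, under OHT unstimulated and with LPS and then with ethanol unstimulated and with LPS (list adjusted p = 0.768, 0.654, 0.497 and 0.734). Postn, a matrix protein of stromal cells, was higher in Rad21-TEV cells by 2.59 and 3.19 under OHT and by 2.80 and 3.13 with ethanol, unstimulated and with LPS. Trf, which encodes transferrin, was the only called one of 11 hepatocyte markers in these 4 comparisons and was higher in each (list adjusted p = 0.736, 0.163, 0.764 and 0.753). Cohesin genes split within the list: Stag1, Stag2 and Nipbl were higher in all 4 comparisons, while 8, 9, 7 and 7 of 16 members were lower (list adjusted p = 0.228, 0.0587, 0.198 and 0.197). Klra3, of the Ly49 receptor family, was higher by 4.53, 5.10, 4.24 and 4.69, but members of this family share sequence, so its counts are uncertain.

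A hypothesis was that genes lowered by OHT in unstimulated Rad21-TEV cells span more DNA than other genes. The 559 lowered genes had a median span of 30.2 kb, against 22.1 kb in 10000 draws matched on mean expression (95% of draws 19.4 to 24.95 kb; one-sided permutation p = 1e-04, the smallest the draws can give). The 188 raised genes had 28.0 kb, against 22.8 kb (18.1 to 28.0 kb; permutation p = 0.0257). The span of the raised genes thus lay inside the 95% of draws but at their upper edge, and lowered and raised genes were not tested against each other. Long genes may be lowered more often, but a trait of lowered genes alone is not shown. The drug is confounded with cleavage here.

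A hypothesis was that lowered genes lie next to each other on the chromosomes. There were 54 adjacent pairs among the 559 lowered genes, against a median of 19 in 10000 expression-matched draws (12 to 28; one-sided permutation p = 1e-04, the smallest possible), and 47 pairs without overlapping genes, against 17 (10 to 26; p = 1e-04). Regional effects of cohesin loss may be one source, and shared regulation of neighbours another, which these counts do not separate. The drug is confounded with cleavage in this test too. Near-identical paralogs were not left out, and neighbours among the raised genes were not counted.

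A hypothesis was that LPS-induced genes are changed by OHT after LPS more often than others. Of the 909 genes induced in wild-type cells 31.7% were called for OHT after LPS in either direction, against 11.6% of matched genes (9.57 to 13.4%; one-sided permutation p = 1e-04, the smallest possible) and 12.2% when matched on LPS-treated levels (10.3 to 14.3%; p = 1e-04). The excess may reflect an effect of OHT on inducible genes in both directions, and it does not separate the drug from cleavage. In resting cells 46 of the 909 were raised and 82 lowered, and no such draws were made there. The excess is therefore not shown to belong to the stimulated state.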
